A study of Mus musculus with 12 samples.

How the data were processed

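RNA was sequenced from tibialis anterior muscle of mice, in 12 libraries that form 4 groups of 3 by genotype label (WT or KO) and time (ZT10 or ZT22). Per the labels, the muscle was flash frozen and RNA was extracted with Trizol and an RNeasy kit. The submitters' processing notes name HISAT2, HTSeq, DESeq2 1.8.2 and the mouse builds GRCm38 and mm10. They state no role or order for these. The annotation used for counting and the strand setting are not given in the sources used here. The authors deposited 1 table with a column of FPKM values per library (fragments per kilobase of transcript per 1e+06 fragments), whose header does not name the unit. The unit was read from the values: multiplied by annotated transcript length in kb and summed, they came to between 1012059 and 1075965 per library. The authors also deposited log2 fold changes for 4 pairs of groups, which by comparison with the library columns are the second-named group over the first. The authors' p-value and q-value columns for the same pairs were counted at 0.05 as deposited, and the model behind them is not given in the sources used here.

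The table had 14583 entries, of which 82 held no values and 230 repeated another exactly; for Plin2, which had 2 differing entries, the one with the higher mean was kept. This left 14270 genes, 14081 of which matched a GENCODE M21 gene by symbol and took their position and median transcript length from it. No mitochondrially encoded gene was in the table, and 0 library columns were left unused. Depth was not given as counts, so it was estimated from the step between low values of genes of known length, at 11.9 to 14.71 in units of 1e+06 fragments per library. The low values followed whole multiples of that step only weakly (mean cosine 0.217 to 0.34 per library), so the estimates are rough. These estimates carry no interval, and no limits for values of 0 were computed from them.

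Groups were taken from the sample titles. Genes with a mean of at least 1 FPKM (9953) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. One model with a mean per group was fitted to the 12 libraries, with an intensity trend in the empirical Bayes step, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The design had been written for counts, with this fit as the stated fallback for normalised values, and the groups, comparisons, gene lists, first set of other settings and naming rule were fixed before the data were examined. Of 46 gene lists, 44 had a tested gene, and 2 had none. Lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over lists within a comparison; camera with an estimated correlation and fry were run beside it. Of 52 list calls at the preset correlation, 0 held with an estimated correlation, and fry, which asks whether a list moves on balance without comparing it to other genes, called 33 of them. In the lists that passed, the median, the mean and the test had 1 sign.

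Genes were named by a rule. It covered Nr1d1, Nr1d2, Thra, the clock list and members of the lists used as checks. It added the 10 strongest rises and falls among called genes with separated groups. It also took the 4 members with the smallest adjusted p or the member with the highest mean in any other list, and the 15 smallest adjusted p in the test of the difference between times. Predicted genes were left out. Hdac3 was chosen after its values were seen.

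The test was tried on simulated data for the comparison of KO with WT at ZT10. Values were drawn from normal distributions with 1 mean per gene in all groups and the gene's residual SD, and 50 of the 9953 genes were changed at each size. It recovered 29 of 50 (58%) at 1.5-fold and 50 of 50 (100%) at 2-fold, 4-fold and 8-fold, with 13 false calls among 192. The sizes were set on the log2(FPKM + 1) scale, where the same fold in FPKM is a smaller change for weakly expressed genes. All groups had the same SD, so a group with a larger spread was not covered.

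The alternatives tried were a pseudocount of 0.1, no filter on low values, the replicate number as a block, only the groups compared, robust empirical Bayes and leaving out each library in turn. Median-of-ratios scaling of the FPKM values and removal of a transcript length trend from each library (lowess, span 0.3) were chosen after seeing the data. The edgeR and DESeq2 tests, their size factors and a filter on low counts, chosen in advance for counts, were not run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, depth and plots.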

Results

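Gene expression was measured by RNA sequencing in the tibialis anterior, a fast limb muscle of the lower leg, of mice with a skeletal-muscle-specific knockout of the REV-ERB receptors and of wild-type (WT) mice. REV-ERBα (Nr1d1) and REV-ERBβ (Nr1d2) are haem-binding nuclear receptors that repress transcription and form a feedback arm of the circadian clock. The 12 libraries form 4 groups of 3, from each genotype at each of 2 times of day. The sample titles give these times as ZT10 and ZT22, hours of zeitgeber time after lights on, and the groups were taken from the titles. The series' design text gives ZT0 and ZT12 instead, so the clock time of each group is uncertain, while which libraries belong together is not. The labels describe the replicates as separate samples and say no more about them. The depth of a library was roughly estimated from the value of a single fragment in weakly expressed genes. It came to 12.05 to 14.71 at ZT10 and 11.9 to 14.39 at ZT22, in units of 1e+06 fragments. The design gives KO against WT at each time and ZT22 against ZT10 in each genotype, and a further comparison asks whether the difference between genotypes changed with time. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Errors of log2 differences are standard errors from limma with n = 3 against 3, which use 1 estimate of spread per gene from all 12 libraries.

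The targeted genes did not carry the direction of their labels. Nr1d1 stood at 32.1 ± 4.71 FPKM in WT and 427 ± 72.1 FPKM in the libraries labelled KO at ZT10 (SD, n = 3), and at 48.2 ± 8.88 and 350.4 ± 20.99 FPKM at ZT22. The log2 differences were 3.69 ± 0.15 and 2.85 ± 0.15 (limma adjusted p = 3.19e-08 and 2.5e-07), and the 3 libraries labelled KO lay above the 3 WT libraries at both times. Nr1d2 was at 41.2 ± 3.24 FPKM in WT and 39.1 ± 2.25 FPKM in the libraries labelled KO at ZT10, a log2 difference of -0.07 ± 0.08 (adjusted p = 0.594), and at ZT22 it was higher by 0.36 ± 0.08 (adjusted p = 0.0078). Values per gene cannot see the loss of single exons from a transcript that is still made, so they do not check the labels of such a knockout. The word KO below stands for the label of a library. Nr1d1 lies on the minus strand of chromosome 11 from 98767932 to 98775333 (GRCm38, GENCODE M21), and its span overlaps by 1075 bp, from 98767932 to 98769006, that of Thra, the thyroid hormone receptor α gene on the plus strand (98740638 to 98769006). Exons of the genes share 263 bp, from 98768157 to 98768419, between the last exon of Nr1d1 and that of one Thra transcript form. Whether the counting used strand is not given in the sources used here, so it is not known to which gene, if any, reads in the overlap were counted. Thra fell in the libraries labelled KO, by 0.74 ± 0.10 on the log2 scale at ZT10 and by 0.70 ± 0.10 at ZT22 (limma adjusted p = 0.000343 and 0.000514). Nr1d2 lies on the minus strand of chromosome 14 from 18204054 to 18239127.

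**Figure D1:**
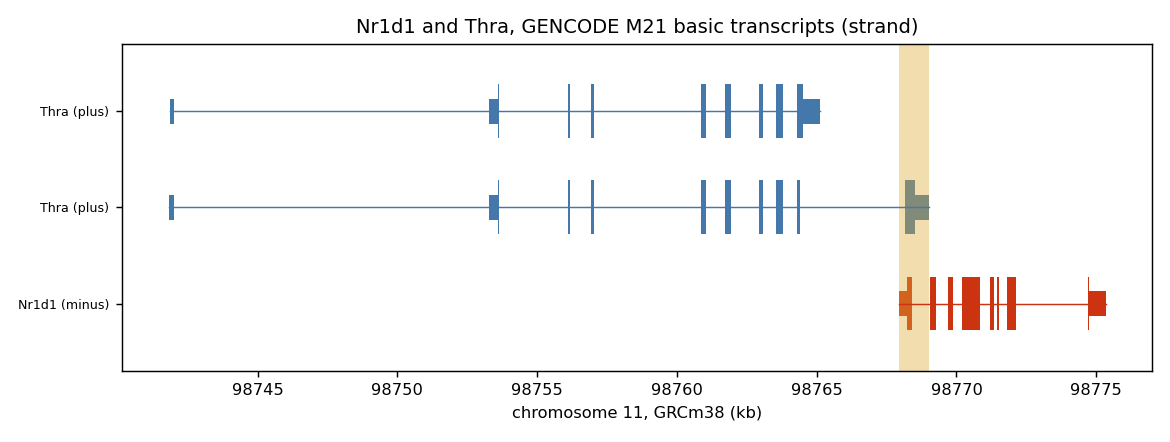
Map of Nr1d1 and Thra on chromosome 11 (GRCm38, position in kb), with 1 line per GENCODE M21 basic transcript, tall boxes for coding exons and low boxes for untranslated exons. The shaded band is the 1075 bp in which the ends of the genes overlap on opposite strands.

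**Figure D2:**
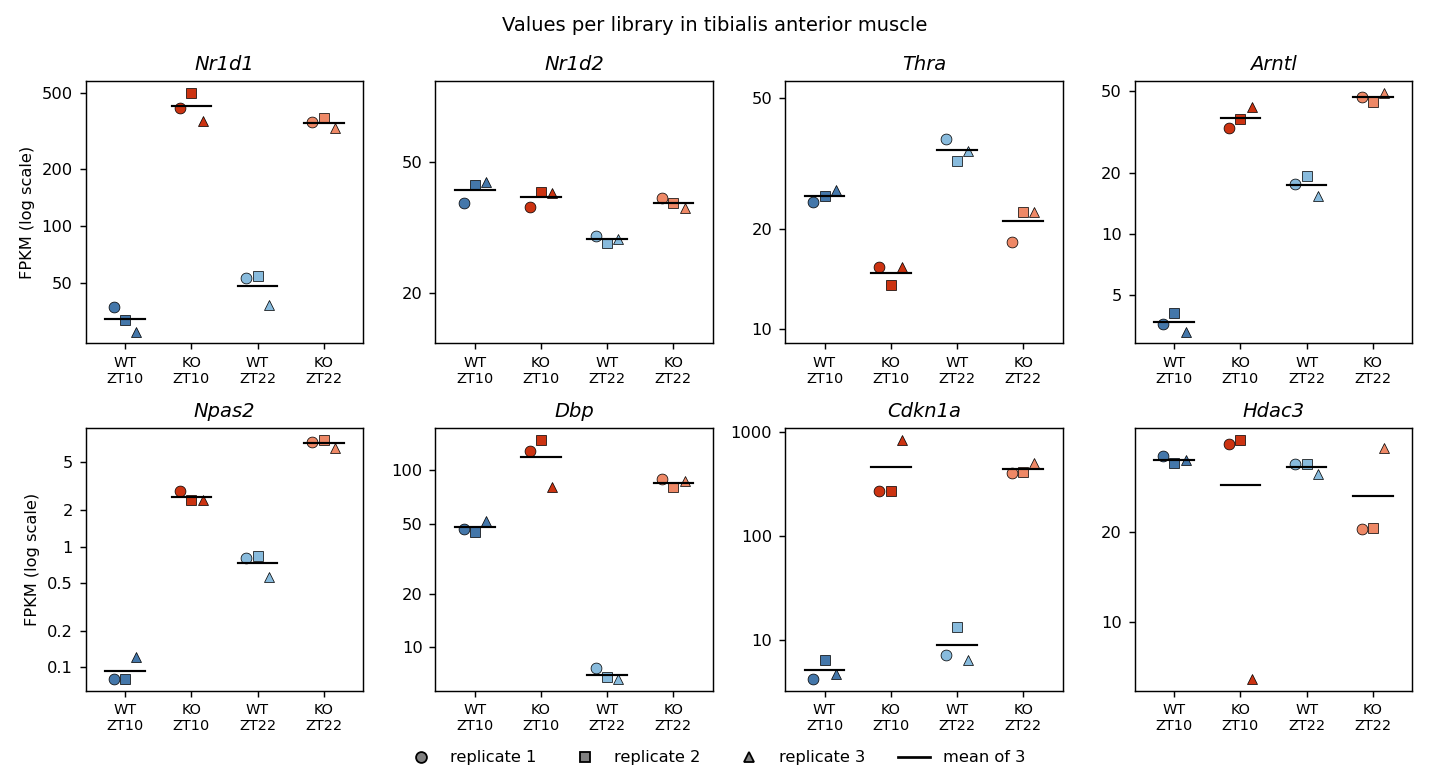
FPKM of 8 genes in each of the 12 libraries (log axes, a different range per gene); symbols give the replicate number and the bar the mean of 3. Nr1d1 was between 27.6 and 54.0 FPKM in the 6 WT libraries and between 327.7 and 503 FPKM in the 6 labelled KO, while Hdac3 was at 6.48 FPKM in KO ZT10 replicate 3.

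At ZT10 the genes that differed strongly between the libraries labelled KO and WT included the cell cycle inhibitor Cdkn1a (p21), the muscle acetylcholine receptor subunit Chrna1 and the core clock activator Arntl (BMAL1). Cdkn1a rose from 5.12 ± 1.12 to 460.7 ± 329.1 FPKM (SD, n = 3; log2 difference 6.03 ± 0.37), Chrna1 from 2.5 ± 0.51 to 59.7 ± 18.5 FPKM (4.09 ± 0.19) and Arntl from 3.68 ± 0.39 to 37.2 ± 4.53 FPKM (3.03 ± 0.11). Carbonic anhydrase III (Car3), an abundant enzyme of muscle fibres, fell from 1350.0 ± 142.6 to 142.5 ± 69.0 FPKM, and the lysine methyltransferase Smyd2 from 186 ± 23.8 to 24.3 ± 8.74 FPKM (log2 differences -3.35 ± 0.45 and -2.93 ± 0.19). Car3 is also on the list of adipocyte markers read below, so its cell source in whole muscle is uncertain. Across the 9953 genes tested, 1425 differed (limma, Benjamini-Hochberg adjusted p under 0.05), 533 higher and 892 lower in KO. Of these, 119 were at least 2-fold higher and 114 at least 2-fold lower, and the 3 libraries of one group lay wholly above or below the other in 30.2% of genes, where chance gives 10%. Other strong rises were the JNK scaffold Mapk8ip1 (3.89 ± 0.19), the glutathione transferase Gstm7 (3.47 ± 0.15) and the muscle phosphatase Dupd1 (2.97 ± 0.13). Other strong falls were the carboxylesterase Ces1d (-2.71 ± 0.25), the peptide transporter family member Slc15a5 (-2.60 ± 0.17), the glycogen-binding protein Stbd1 (-2.57 ± 0.38), the secreted Wnt modulator Dkk3 (-2.44 ± 0.21) and the sphingosine-1-phosphate transporter Spns2 (-2.39 ± 0.18). The myosin-binding protein Mybph and the slow myosin light chain Myl2 rose by 5.0 ± 0.56 and 3.55 ± 0.72, to levels that varied widely among the libraries labelled KO (280.9 ± 229.5 and 31.7 ± 20.8 FPKM, SD, n = 3). The count fell to 858 without WT ZT10 replicate 2, to 847 without WT ZT10 replicate 3 and to 748 when only these 6 libraries were fitted. Scaling the libraries by median of ratios gave 745 higher and 660 lower, so the excess of falls depended on the scaling.

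Clock genes as a list shifted upward at ZT10 by camera at its preset correlation. Of the 23 tested members of the circadian clock list, 11 rose, 2 fell and 10 did not pass (11 rose and 4 fell adjusted over the list alone; camera adjusted p = 1.02e-05, adjusted p = 0.221 with an estimated correlation). Of 6 clock genes with binding elements shared by REV-ERB and ROR receptors, 5 rose: Arntl, Npas2 (1.71 ± 0.10), Clock (1.15 ± 0.13), Nfil3 (2.21 ± 0.29) and Cry1 (0.86 ± 0.11). The median of this list was 1.43 (5 rose adjusted over the list alone; camera adjusted p = 8.12e-07, adjusted p = 0.196 with an estimated correlation). The log2 difference of Npas2, which was at 0.093 ± 0.023 FPKM in WT, became 3.80 with a pseudocount of 0.1. Among 12 clock outputs driven through E-boxes and D-boxes, 4 rose and none fell, namely Dbp (1.26 ± 0.17), Ciart (1.30 ± 0.19), Cry2 (0.88 ± 0.11) and Tef (0.71 ± 0.11) (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0413, adjusted p = 0.436 with an estimated correlation). That call was lost under median-of-ratios scaling (adjusted p = 0.063) and with the transcript length trend removed (0.0582). The period genes Per1 (-0.23 ± 0.30), Per2 (-0.33 ± 0.11) and Per3 (-0.14 ± 0.15) did not pass.

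At ZT10 the list of branched-chain amino acid breakdown passed upward and that of glycogen metabolism downward, by camera at its preset correlation. Of 25 genes of branched-chain amino acid breakdown, 8 rose, none fell and 17 did not pass (13 rose and none fell adjusted over the list alone; camera adjusted p = 1.42e-06, adjusted p = 0.244 with an estimated correlation). They included the aminotransferase Bcat2, which takes the first step (0.80 ± 0.09), and the leucine-pathway dehydrogenase Ivd (1.07 ± 0.15). Of 17 genes of glycogen metabolism, 7 fell, 1 rose and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0236, adjusted p = 0.244 with an estimated correlation). Those that fell included Ugp2, which makes UDP-glucose (-1.22 ± 0.15), the phosphorylase kinase subunit Phka1 (-0.91 ± 0.14) and the glycogen-targeting phosphatase subunit Ppp1r3a (-0.80 ± 0.14). Among 24 genes of glucose uptake and glycolysis, 7 fell and 3 rose (12 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.108), although it did without KO ZT10 replicate 3 (0.0275). Hexokinase Hk2 (-0.70 ± 0.12), the glucose transporter Slc2a4 (-0.44 ± 0.07) and the transporter-trafficking regulator Tbc1d1 (-2.13 ± 0.31) fell, while Ldhb (0.96 ± 0.16), the lactate dehydrogenase subunit of oxidative fibres, rose. The lipolysis genes Pnpla2 (0.67 ± 0.08) and Plin5 (1.70 ± 0.23) rose, and the pyruvate dehydrogenase phosphatase Pdp1 fell (-1.13 ± 0.07). The NAD salvage enzyme Nampt (-0.96 ± 0.08) and the myokine genes Il15 (-0.93 ± 0.18) and Fndc5 (-0.76 ± 0.13) also fell. The nuclear-encoded respiratory chain had 1 gene higher and none lower among 48 (none adjusted over the list alone and 5 at an unadjusted p under 0.05 by limma; camera adjusted p = 0.105). The limma adjusted p of the members named in this paragraph was at most 0.00487, and the 3 libraries of one group lay outside the range of the other for each.

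The lists of calcium handling and of denervation and the neuromuscular junction passed upward at ZT10 in the same test. Of 21 calcium-handling genes, 6 rose and 1 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.0244, adjusted p = 0.196 with an estimated correlation). Myoregulin (Mrln), a peptide inhibitor of the calcium pump SERCA, rose by 1.94 ± 0.13, the voltage sensor Cacna1s by 0.85 ± 0.08 and the calcium buffer Casq2 by 1.73 ± 0.21, while the fast-fibre pump Atp2a1 was at 0.01 ± 0.09. Of 15 genes of denervation and the neuromuscular junction, 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.196 with an estimated correlation). Besides Chrna1 they included the receptor kinase Musk (1.05 ± 0.19) and the acetylcholinesterase anchor Colq (0.83 ± 0.16), both components of the synapse. Of 44 ribosomal protein genes, 12 rose, none fell and 32 did not pass, among them Rplp0 at 0.55 ± 0.11 (23 rose adjusted over the list alone; camera adjusted p = 2.19e-11, adjusted p = 0.397 with an estimated correlation). Of the 44 gene lists with a tested gene, 8 passed at ZT10, and 7 of these stayed past the threshold in each of 4 other settings, in which adjusted p ran from 2.21e-12 to 0.063.

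At ZT22 the largest rises in the libraries labelled KO were of Cdkn1a, Chrna1 and the clock output transcription factor Dbp. Cdkn1a rose from 9.01 ± 3.79 to 444 ± 56.0 FPKM (SD, n = 3; log2 difference 5.53 ± 0.37), Chrna1 from 3.57 ± 0.57 to 60.8 ± 9.33 FPKM (3.75 ± 0.19) and Dbp from 6.97 ± 0.52 to 85.4 ± 4.66 FPKM (3.44 ± 0.17). Ces1d fell from 30.0 ± 9.45 to 1.78 ± 0.18 FPKM (-3.43 ± 0.25) and Smyd2 from 157.8 ± 7.91 to 23.2 ± 4.07 FPKM (-2.73 ± 0.19). In all, 1826 of the 9953 genes differed (limma adjusted p under 0.05), 710 higher and 1116 lower in the libraries labelled KO. At least 2-fold changes numbered 85 higher and 94 lower, and 41.5% of genes separated the groups without overlap, against 10% by chance. Other strong changes were rises of Mapk8ip1 (3.22 ± 0.19), Dupd1 (2.86 ± 0.13), Gstm7 (2.79 ± 0.15), the tubulin polyglutamylase Ttll7 (2.59 ± 0.28) and the phospholipase Pla2g7 (2.41 ± 0.11). Car3 (-3.23 ± 0.45), Slc15a5 (-2.39 ± 0.17), Stbd1 (-2.28 ± 0.38), the small GTPase Rhou (-2.23 ± 0.16), the potassium channel subunit Kcng4 (-2.19 ± 0.31) and the ciliary neurotrophic factor receptor Cntfr (-1.95 ± 0.18) fell. The count was 1110 without WT ZT22 replicate 1, 1035 without WT ZT22 replicate 2, 1161 without KO ZT22 replicate 1 and 2270 when only these 6 libraries were fitted. Median-of-ratios scaling gave 910 higher and 917 lower.

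The clock list passed again. Of the 23 genes tested, 13 rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 9.03e-10, adjusted p = 0.112 with an estimated correlation). Of the 6 genes with REV-ERB and ROR elements, Npas2 (2.24 ± 0.10), Nfil3 (1.46 ± 0.29), Arntl (1.38 ± 0.11), Clock (1.24 ± 0.13) and Cry1 (1.03 ± 0.11) rose. The count of 5 was the same adjusted over the list alone (camera adjusted p = 1.71e-05, adjusted p = 0.138 with an estimated correlation). Of the 12 E-box and D-box outputs, 5 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000394, adjusted p = 0.185 with an estimated correlation). Those that rose included Dbp, Ciart (1.49 ± 0.19), Cry2 (1.28 ± 0.11) and Tef (0.79 ± 0.11). Per1, Per2 and Per3 did not pass, at 0.34 ± 0.30, 0.22 ± 0.11 and 0.14 ± 0.15.

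Some glycolytic and respiratory genes were lower at ZT22 in the libraries labelled KO. Of 24 genes of glucose uptake and glycolysis, 11 fell and none rose (13 fell adjusted over the list alone; camera adjusted p = 0.000394, adjusted p = 0.116 with an estimated correlation). They included triose-phosphate isomerase Tpi1 (-0.95 ± 0.10), the muscle enolase Eno3 (-0.77 ± 0.09), the muscle phosphoglycerate mutase Pgam2 (-0.69 ± 0.11) and lactate dehydrogenase Ldha (-0.64 ± 0.08). Of 48 nuclear-encoded respiratory chain genes, 17 fell and none rose, among them the complex I subunits Ndufs7 (-0.67 ± 0.10) and Ndufs8 (-0.54 ± 0.09) and cytochrome c1 (Cyc1, -0.50 ± 0.08). The respiratory count was 19 adjusted over the list alone (camera adjusted p = 1.71e-05, adjusted p = 0.772 with an estimated correlation). With the transcript length trend removed, 11 respiratory genes fell and 1 rose, and the median went from -0.22 to -0.13 (camera adjusted p = 0.00116). Of 25 genes of branched-chain amino acid breakdown, 8 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00391, adjusted p = 0.615 with an estimated correlation). Bcat2 rose by 0.58 ± 0.09 and the dehydrogenases Aldh6a1 and Acadsb by 0.57 ± 0.08 and 0.63 ± 0.10. Klf15, a transcription factor that activates this pathway in muscle, rose by 0.69 ± 0.15. The mitochondrial pyruvate carrier subunit Mpc2 fell by 0.84 ± 0.09, the lipid droplet coat protein Plin2 by 1.05 ± 0.11 and Il15 by 1.17 ± 0.18, while Pnpla2 rose by 0.88 ± 0.08. The limma adjusted p of the members named in this paragraph was at most 0.00879.

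The lists of proteasome subunits, autophagy and mitophagy, and myogenic and regeneration genes passed upward at ZT22 by camera at its preset correlation. Of 31 proteasome subunit genes, 12 rose, 3 fell and 16 did not pass (15 and 3 adjusted over the list alone; camera adjusted p = 0.000185, adjusted p = 0.615 with an estimated correlation). Psmc6 and Psmd14, parts of the regulatory particle, rose by 0.46 ± 0.06 and 0.48 ± 0.08, while the catalytic subunit gene Psmb6 fell by 0.44 ± 0.09. Of 32 genes of autophagy and mitophagy, 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.00529, adjusted p = 0.495 with an estimated correlation). The lysosomal membrane protein gene Lamp1 rose by 0.85 ± 0.07 and the mitophagy receptor gene Bnip3 by 0.64 ± 0.10, whereas Map1lc3a, which encodes an LC3 protein of the autophagosome, fell by 1.30 ± 0.10. Among 11 myogenic and regeneration genes, 3 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0385, adjusted p = 0.513 with an estimated correlation). Besides Cdkn1a they included the myogenic transcription factor Myod1 (1.39 ± 0.20), and the list's call was lost with the transcript length trend removed (adjusted p = 0.0562) and with the replicate number as a block (0.056). Mrln rose by 2.29 ± 0.13 and Musk by 1.73 ± 0.19, while the lists of calcium handling (median -0.02, mean 0.18, test upward) and of denervation did not pass at this time (camera adjusted p = 0.138 and 0.287). Grb14, an adaptor that binds the insulin receptor, fell by 1.94 ± 0.33. None of the 44 ribosomal protein genes passed by limma, over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05), and the list was at a median of -0.03 (camera adjusted p = 0.895). With the length trend removed its median was 0.07, and 3 of its genes were called higher and none lower (camera adjusted p = 0.214). Of the 44 lists, 13 passed and 12 of these stayed past the threshold in each of 4 other settings, in which adjusted p ran from 8.86e-10 to 0.0562.

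**Figure D3:**
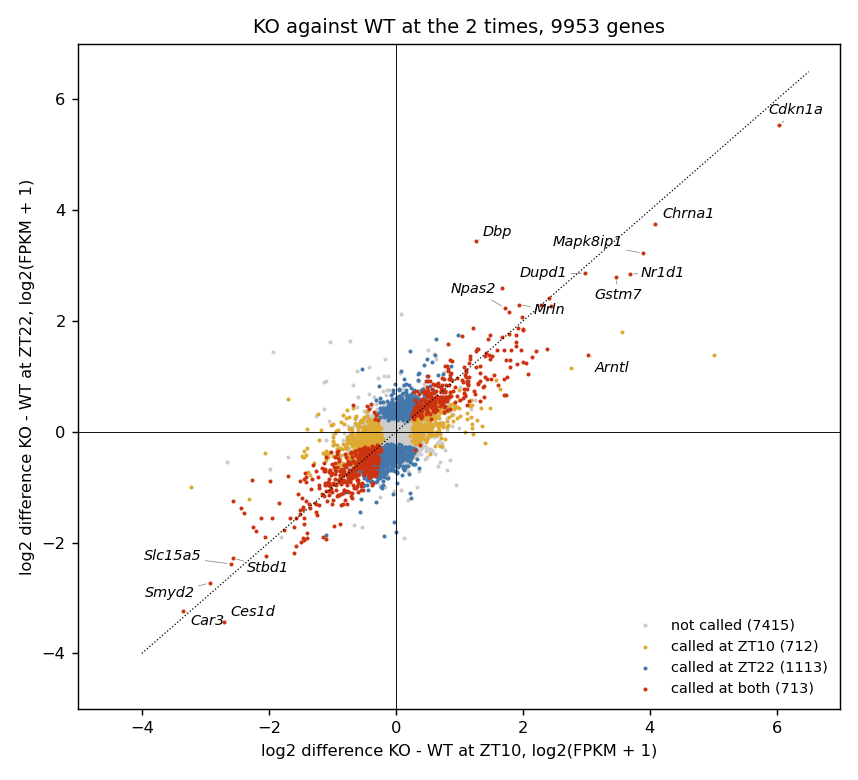
Log2 difference between libraries labelled KO and WT at ZT10 (horizontal) and ZT22 (vertical) for the 9953 genes tested, on the log2(FPKM + 1) scale; each point is a gene, coloured by the times at which it was called, and the dotted line marks equal differences. The 713 genes called at both times lie mostly near that line, with Dbp above it and Arntl below.

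Much of the difference between genotypes was shared by the 2 times. Called higher at both were 281 genes and called lower at both 422, where independent lists of these sizes would share 38 and 100, and 10 genes were called in opposite directions. The log2 differences at the 2 times correlated at Pearson r = 0.651 across genes, which are not independent replicates. Cdkn1a, Chrna1, Nr1d1, Npas2 and Bcat2 were among those higher at both, and Car3, Smyd2, Ces1d, Pdp1, Nampt and Il15 among those lower at both. The 2 comparisons share no library, but their standard errors come from 1 estimate of spread per gene. A test of the difference itself, on all 12 libraries, called 4 genes (limma adjusted p under 0.05; 1696 at an unadjusted p under 0.05). Arntl rose more in KO at ZT10 than at ZT22, by 1.64 ± 0.15 on the log2 scale (adjusted p = 0.0012). Dbp rose more at ZT22, by 2.18 ± 0.24 (adjusted p = 0.00399). The glycerophosphocholine phosphodiesterase Gpcpd1 (1.15 ± 0.16) and the amino acid transporter family member Slc38a10 (-1.09 ± 0.15) had adjusted p = 0.023 each. The count was 77 without WT ZT10 replicate 1, 68 without KO ZT10 replicate 1, 47 without KO ZT10 replicate 3, 18 without WT ZT22 replicate 3, and 2 without WT ZT10 replicate 2 or 3, KO ZT10 replicate 2, WT ZT22 replicate 1 or KO ZT22 replicate 1. Gpcpd1 and Slc38a10 both failed in those last 5 settings and without KO ZT22 replicate 2, Gpcpd1 also without KO ZT22 replicate 3 and Slc38a10 also without WT ZT22 replicate 2, at adjusted p between 0.0744 and 0.117.

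Between ZT10 and ZT22 in WT muscle, clock genes changed in opposite directions. Arntl rose from 3.68 ± 0.39 FPKM at ZT10 to 17.4 ± 1.98 at ZT22 (SD, n = 3; log2 difference 1.97 ± 0.11), and Dbp fell from 47.8 ± 3.63 to 6.97 ± 0.52 FPKM (-2.62 ± 0.17). Chac1, which encodes a glutathione-degrading enzyme, fell from 91.2 ± 29.1 to 5.04 ± 0.03 FPKM (-3.89 ± 0.25). Pyruvate dehydrogenase kinase Pdk4 fell from 619 ± 59.5 to 153.9 ± 71.5 FPKM and the uncoupling protein Ucp3 from 166 ± 8.82 to 44.1 ± 13.7 FPKM (log2 differences -2.13 ± 0.39 and -1.94 ± 0.30). Across genes, 2404 differed (limma adjusted p under 0.05), 1830 higher and 574 lower at ZT22, and 43.6% of genes separated the groups, against 10% by chance. At least 2-fold changes numbered 87 higher and 39 lower. The processed pseudogenes Rpl31-ps12 (3.61 ± 0.33) and Rpl37rt (2.83 ± 0.20) were among the strongest rises, from near 0 FPKM, and a pseudocount of 0.1 gave 5.52 for the former. The lipolysis inhibitor G0s2 rose by 3.15 ± 0.52 and the lipid-droplet enzyme Pnpla3 by 1.68 ± 0.22, while the cytokine-signalling suppressor Cish fell by 2.48 ± 0.42 and the arrestin-like gene Arrdc2 by 2.28 ± 0.28. The times also differed in ways that touched all genes. The median of all genes was higher at ZT22 by 0.095 in WT and 0.11 in KO, log2 differences rose with transcript length (Spearman rho 0.373 in WT and 0.468 in KO across 9901 genes), and scaling by median of ratios gave 1188 higher and 1127 lower in WT. With the length trend removed, 1824 genes were called in WT, 1368 of them called before. Of the 2404 called before, 39 then took the other sign. The count in WT was 1406 without WT ZT10 replicate 1, 1477 without WT ZT22 replicate 1 and 1290 without WT ZT22 replicate 2.

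Of the 23 clock genes, 7 rose and 6 fell from ZT10 to ZT22 in WT (7 and 7 adjusted over the list alone; camera adjusted p = 0.187). Of the 6 genes with REV-ERB and ROR elements, 5 rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00261, adjusted p = 0.369 with an estimated correlation), led by Arntl, Clock (1.00 ± 0.13) and Npas2 (0.66 ± 0.10). Npas2 was at 0.08 to 0.12 FPKM at ZT10 and 0.56 to 0.84 FPKM at ZT22 in WT, so the log2(FPKM + 1) scale understates its rise. Of the 12 E-box and D-box outputs, 5 fell and none rose (6 fell adjusted over the list alone; camera adjusted p = 3.86e-05, adjusted p = 0.215 with an estimated correlation), led by Dbp, Per2 (-0.99 ± 0.11) and Ciart (-1.38 ± 0.19). Nr1d2 fell by 0.48 ± 0.08, while Nr1d1 was higher at ZT22 (37.99 to 54.0 FPKM in WT, against 27.64 to 37.03 FPKM at ZT10). Both had an unadjusted p under 0.05 by limma. With the length trend removed, Nr1d1 was not called higher. Of 17 glucocorticoid-responsive genes, 9 fell and none rose, and the median lay 0.84 below that of all genes (11 fell adjusted over the list alone; camera adjusted p = 3.37e-08, adjusted p = 0.215 with an estimated correlation). They included the NF-κB inhibitor Nfkbia (-1.39 ± 0.14), glutamine synthetase Glul (-1.15 ± 0.21), Fam107a (-0.73 ± 0.11) and Pdk4. The ubiquitin ligase Trim63 (MuRF1), a gene of muscle atrophy, fell by 1.39 ± 0.28. Of 48 nuclear-encoded respiratory chain genes, 20 fell and none rose (22 fell adjusted over the list alone; camera adjusted p = 1.78e-12, adjusted p = 0.537 with an estimated correlation), among them Cox6c (-0.97 ± 0.11), Cox4i1 (-0.66 ± 0.08) and Cox5b (-0.61 ± 0.09), subunits of cytochrome c oxidase. The interferon response list had 7 of 15 genes higher and none lower (8 higher adjusted over the list alone; camera adjusted p = 0.0231, adjusted p = 0.623 with an estimated correlation), with Irf7 at 0.92 ± 0.16. With the length trend removed, 1 interferon gene was higher (camera adjusted p = 0.00385). Of the 44 lists, 15 passed and 11 of these stayed past the threshold in each of 4 other settings, in which adjusted p ran from 6.18e-12 to 0.334. Lower by camera but with fewer calls were branched-chain amino acid breakdown (6 of 25 genes lower, adjusted p = 0.000764), glucose uptake and glycolysis (4 lower and 1 higher of 24, 0.00148), glycogen metabolism (2 of 17 lower, 0 adjusted over the list alone, 0.0231) and fatty acid uptake and oxidation (3 lower and 1 higher of 30, 0.00818). So were muscle atrophy (4 lower and 2 higher of 24, 7 and 2 adjusted over the list alone, 0.0169), the proteasome (5 of 31 lower, 0.000289), fast fibre genes (3 of 14 lower, 0.0175) and immediate early genes (1 lower and 1 higher of 20, 1 lower adjusted over the list alone, 0.00658, lost under median-of-ratios scaling at 0.0632). Where no other count is given, those adjusted over the list alone were the same, and with an estimated correlation the 8 lists had adjusted p between 0.215 and 0.702. The calls of fatty acid uptake and oxidation, fast fibre and immediate early genes were lost with the length trend removed (adjusted p = 0.0883 each). The ribosomal protein list, with 9 genes lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 7.62e-05, adjusted p = 0.623 with an estimated correlation), reached that 0.334 with the length trend removed.

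Between the same times in the libraries labelled KO, the falls of Chac1, Angptl4 and the transcription factor gene Cebpb were among the strongest. Angptl4, a secreted inhibitor of lipoprotein lipase, fell from 50.9 ± 35.3 to 3.84 ± 2.27 FPKM (SD, n = 3; log2 difference -3.33 ± 0.52), Chac1 from 35.4 ± 6.80 to 2.49 ± 1.25 FPKM (-3.43 ± 0.25) and Cebpb from 57.3 ± 19.97 to 9.47 ± 1.03 FPKM (-2.43 ± 0.19). Rpl31-ps12 (4.28 ± 0.33) and Rpl37rt (3.63 ± 0.20) rose here too, the latter by 6.20 with a pseudocount of 0.1. Pdk4 (-1.82 ± 0.39), Ucp3 (-2.10 ± 0.30), Arrdc2 (-2.92 ± 0.28) and Trim63 (-1.28 ± 0.28) fell as in WT. Npas2 rose by 1.19 ± 0.10 and Ciart fell by 1.19 ± 0.19, while Dbp was at -0.43 ± 0.17 (adjusted p = 0.0574), called at -0.69 without KO ZT10 replicate 3 and at -0.57 under median-of-ratios scaling. In KO 4239 genes differed (limma adjusted p under 0.05), 2872 higher and 1367 lower at ZT22, 160 of them at least 2-fold higher and 57 at least 2-fold lower, and 51.2% of genes separated the groups, against 10% by chance. Median-of-ratios scaling gave 2033 higher and 2184 lower. With the length trend removed 3358 were called, of which 2549 had been called before. Of the 4239 called before, 219 then took the other sign. Higher in both genotypes at ZT22 were 1415 genes and lower in both 417, where independent lists would share 528.1 and 78.8, and 14 were opposite. The larger count in KO than in WT is not itself a test of a difference between genotypes. That test, by limma, called 4 genes, and 1696 of 9953 had an unadjusted p under 0.05, a share above the 0.05 that chance gives. Its median standard error was 0.168, against 0.119 for either time comparison, so smaller differences between genotypes are not excluded.

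Several metabolic lists were lower at ZT22 than ZT10 in the libraries labelled KO, while glycogen metabolism, lipid synthesis and storage, and cholesterol synthesis did not pass (camera adjusted p = 0.619 to 0.958). Of 48 nuclear-encoded respiratory chain genes, 37 fell and none rose, with a median 0.63 below that of all genes (39 fell adjusted over the list alone; camera adjusted p = 1.2e-19, adjusted p = 0.593 with an estimated correlation), among them Ndufa2 (-1.26 ± 0.09), Atp5g1 (-0.98 ± 0.09) and Cox4i1 (-0.92 ± 0.08). With the length trend removed, 32 respiratory genes fell and 2 rose. Of 24 genes of glucose uptake and glycolysis, 13 fell and 1 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.000126, adjusted p = 0.21 with an estimated correlation), with Aldoa at -0.68 ± 0.09 and Ldha at -0.61 ± 0.08. Of 30 genes of fatty acid uptake and oxidation, 13 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.000507, adjusted p = 0.848 with an estimated correlation), including the fatty acid transporter Slc27a1 (-0.57 ± 0.09). Of 25 genes of branched-chain amino acid breakdown, 10 fell and none rose (10 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00133, adjusted p = 0.726 with an estimated correlation), including Bcat2 (-0.65 ± 0.09). Of 16 genes of the tricarboxylic acid cycle, 6 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00133, adjusted p = 0.789 with an estimated correlation). Of 44 ribosomal protein genes, 29 fell and none rose (31 fell adjusted over the list alone; camera adjusted p = 1.26e-13, adjusted p = 0.593 with an estimated correlation), led by Rpl13 (-0.98 ± 0.08) and Rps9 (-0.82 ± 0.08). With the length trend removed, 18 ribosomal protein genes fell and 2 rose, and the median went from -0.35 to -0.17 (camera adjusted p = 0.00352). Rps21, a ribosomal protein gene outside that list, fell by 1.90 ± 0.10. Of 17 glucocorticoid-responsive genes, 7 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.751 with an estimated correlation); Tsc22d3 (-0.83 ± 0.17) fell and Fkbp5 (0.97 ± 0.21) rose. Fast fibre genes (6 of 14 lower, camera adjusted p = 0.00704, adjusted p = 0.726 with an estimated correlation) and calcium handling (6 lower and 2 higher of 21, camera adjusted p = 0.0396, adjusted p = 0.437 with an estimated correlation) also passed, with the same counts adjusted over the list alone. The fast fibre call was lost with the length trend removed (adjusted p = 0.064). So did the sex-linked list (4 of 4 higher in both counts, camera adjusted p = 0.0488, adjusted p = 0.593 with an estimated correlation). That call was lost with the replicate number as a block (adjusted p = 0.0525), with the length trend removed (0.0567), under median-of-ratios scaling (0.0533) and without KO ZT10 replicate 3 (0.0534). The call of the glucocorticoid list was lost without KO ZT10 replicate 3 (adjusted p = 0.0711). Of the 44 lists, 10 passed and 7 of these stayed past the threshold in each of 4 other settings, in which adjusted p ran from 3.46e-20 to 0.0711.

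**Figure D4:**
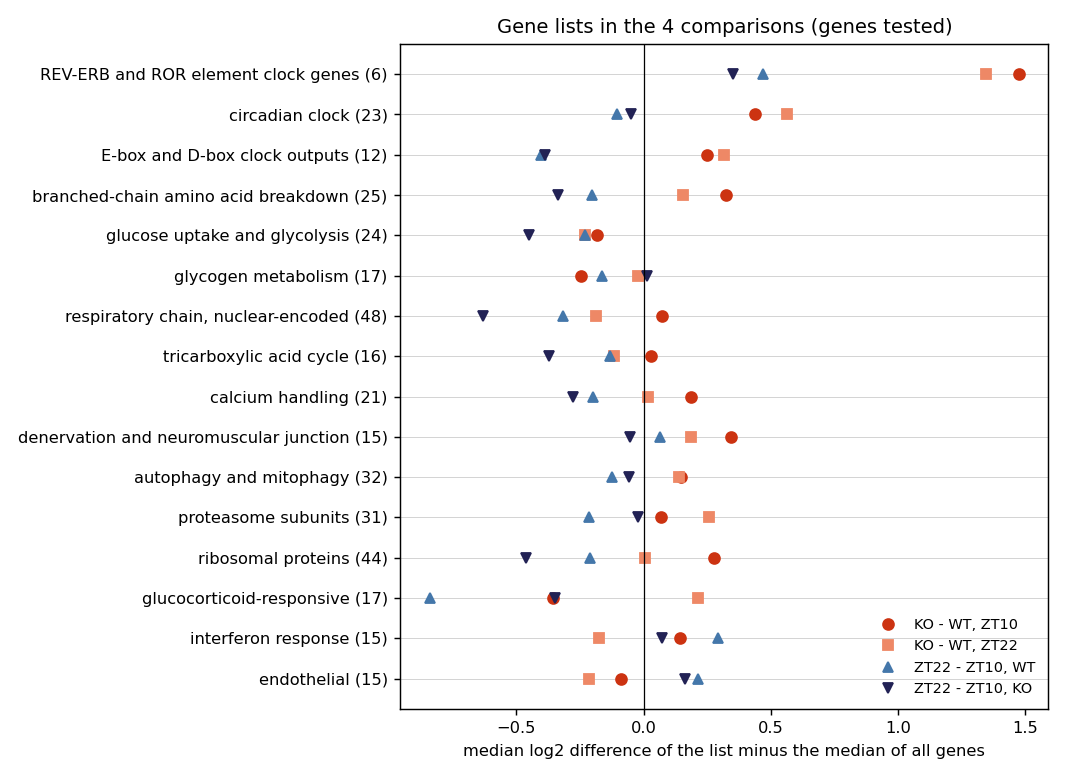
Median log2 difference of 16 gene lists in the 4 comparisons, minus the median of all genes in that comparison (horizontal axis, log2(FPKM + 1) scale); numbers in brackets are the genes tested. REV-ERB and ROR element genes stand highest in both comparisons of libraries labelled KO with WT, and the respiratory chain lowest at ZT22 against ZT10 in KO.

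**Figure D5:**
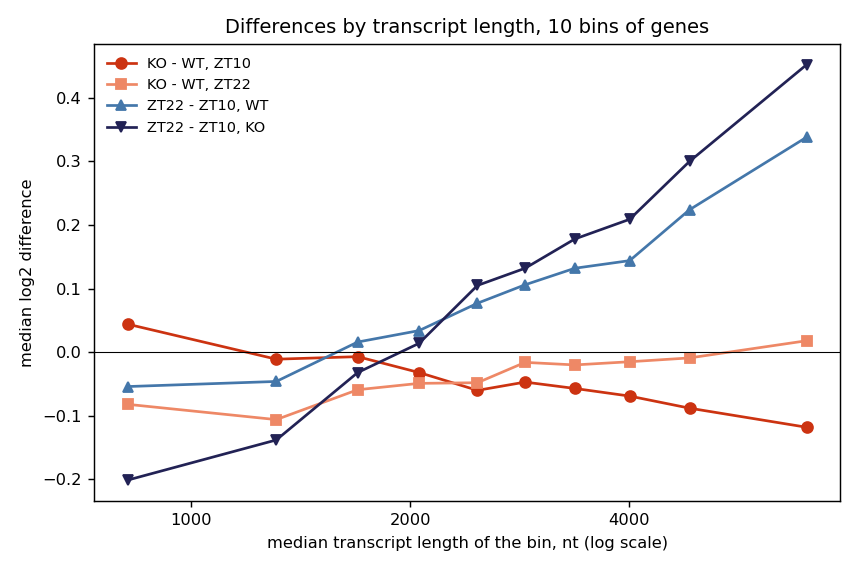
Median log2 difference (vertical) of genes in 10 bins of annotated transcript length (horizontal, nt, log axis) in the 4 comparisons, over 9901 genes with a length. Both comparisons of ZT22 with ZT10 rise with length, from medians of -0.054 in WT and -0.201 in KO in the bin of shortest genes to 0.338 and 0.452 in the bin of longest.

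Markers of other cell types in whole muscle were read as a check of tissue makeup. Endothelial markers differed between the groups: 6 of 15 were higher at ZT22 than ZT10 in WT and none lower (7 higher adjusted over the list alone; camera adjusted p = 0.0231, adjusted p = 0.676 with an estimated correlation). They included the endothelial receptor Kdr (1.29 ± 0.13) and the junction proteins Pecam1 (0.77 ± 0.11) and Cdh5 (0.68 ± 0.13). At ZT22 the same list was lower in the libraries labelled KO than in WT, with 2 genes lower, the same count adjusted over the list alone (camera adjusted p = 0.0161, adjusted p = 0.772 with an estimated correlation), among them Egfl7 (-0.54 ± 0.10). The interferon response list moved with it, with 3 of 15 genes lower in KO at ZT22, the same count adjusted over the list alone (camera adjusted p = 0.0364, adjusted p = 0.725 with an estimated correlation), led by Bst2 (-1.10 ± 0.23). The lists of macrophage, fibro-adipogenic, smooth muscle, satellite cell, tendon, nerve, adipocyte, neutrophil and erythrocyte markers did not pass in these comparisons, with camera adjusted p between 0.0962 and 0.997. In WT, 6 of the 7 erythrocyte markers nevertheless had an unadjusted p under 0.05 between the times (median -0.75). So did 5 of 8 adipocyte markers in KO against WT at ZT10, where the median was 0.55 while the called Car3 and Plin4 fell, against a median of -0.32 at ZT22 (camera adjusted p = 0.571 and 0.287). The change of the adipocyte list between the times had a median of -0.87 and did not pass (camera adjusted p = 0.0999). An unadjusted p under 0.05 was also seen for 3 of 4 nerve markers at ZT22 and, between the times in KO, for 2 of 2 neutrophil and 4 of 6 satellite cell markers. The haemoglobin genes Hba-a1 and Hba-a2 fell by 1.08 ± 0.32 and 1.16 ± 0.30 from ZT10 to ZT22 in WT (limma adjusted p = 0.0281 and 0.0161), while Ank1 of the same list rose by 0.41 ± 0.10. Hba-a2 lost its call without WT ZT10 replicate 2 (0.0564) or 3 (0.0606) or WT ZT22 replicate 3 (0.0558). Hba-a1, whose groups overlapped, lost it without WT ZT10 replicate 2 (0.0866) or 3 (0.104) or WT ZT22 replicate 1 (0.089) or 3 (0.0859), with robust empirical Bayes (0.0517) and with the length trend removed (0.0597). Of the 4 sex-linked genes tested, Uty was higher in KO at ZT22 by 0.43 ± 0.10, and 3 of 4 were higher, the same count adjusted over the list alone (camera adjusted p = 0.0241, adjusted p = 0.378 with an estimated correlation). All 4 lie on chromosome Y and were expressed in each of the 12 libraries. Ddx3y was at 18.83 FPKM or more, Eif2s3y at 28.18, Kdm5d at 2.01 and Uty at 3.34. These values argue against a mix of sexes between the groups.

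In the deposited table, the authors' own q-values under 0.05 numbered 966 for KO against WT at ZT10 (511 higher and 455 lower in KO) and 7864 at ZT22 (3279 and 4585). For ZT22 against ZT10 they numbered 2060 in WT (993 higher and 1067 lower at ZT22) and 2986 in KO (1484 and 1502). The excess of rises at ZT22 in the main fit is thus not in the authors' counts. The columns of the ZT22 comparison of genotypes differed in form from the other 3. Their log2 fold changes lay within 0.05 of the log2 ratio of mean FPKM for 88.8% of 6201 genes, against 4.4% to 20.8% in the other 3, 127 of their q-values are listed as 0 and their highest q is 0.444. Whether they came from another calculation is not given in the sources used here, so the authors' counts at the 2 times were not compared.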

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

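The scaling and transcript length alternatives in this part were chosen after the result was seen, while the test of the difference between times and its random regroupings were planned.

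The difference between genotypes changed between ZT10 and ZT22 for Arntl and Dbp, which encode a core clock activator and a clock output factor. On the log2 scale the difference at ZT22 minus that at ZT10 was -1.64 for Arntl and 2.18 for Dbp (limma adjusted p = 0.0012 and 0.00399). In WT, Arntl was low at ZT10 (3.68 FPKM) and Dbp low at ZT22 (6.97 FPKM), and the libraries labelled KO were high at both times, so each gap was widest at the time when WT was low. Gpcpd1 was lower in KO at ZT10 and higher at ZT22 (log2 differences -0.67 and 0.48, a change of 1.15), and Slc38a10 was higher in KO at ZT10 and level at ZT22 (1.09 and 0.00, a change of -1.09). Both had adjusted p = 0.023. Gpcpd1 lost its call under median-of-ratios scaling (adjusted p = 0.0641), where the change was 1.13, close to the 1.15 before. It also lost it without WT ZT10 replicate 2 (0.106) or 3 (0.0801), KO ZT10 replicate 2 (0.0854), WT ZT22 replicate 1 (0.0759), or KO ZT22 replicate 1 (0.0871), 2 (0.0807) or 3 (0.0971). Slc38a10 lost its call without WT ZT10 replicate 2 (0.106) or 3 (0.0801), KO ZT10 replicate 2 (0.0854), WT ZT22 replicate 1 (0.0759) or 2 (0.0744), or KO ZT22 replicate 1 (0.117) or 2 (0.0807). In these settings the changes stayed at 1.07 to 1.18 for Gpcpd1 and -1.13 to -1.02 for Slc38a10.

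For the count of 4 genes, 7 of 100 random regroupings of the libraries within each time, the real one included, gave as many, so chance cannot be excluded for the count. The highest other regrouping called 130 genes, far above the real count. These regroupings mix the genotypes within a time, so the genotype difference itself enters their counts, and no other structure was tested for.

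For 6 gene lists camera at its preset correlation called a change of the genotype difference between times, while limma called none of their genes over all genes (1696 of 9953 genes at an unadjusted p under 0.05). With an estimated correlation the 6 lists had adjusted p = 0.689 to 0.73, and fry called 0 of them. The medians of the change were -0.27 for the nuclear-encoded respiratory chain (14 of 48 genes lower adjusted over the list alone; camera adjusted p = 2.1e-11) and -0.15 for the tricarboxylic acid cycle (1 lower of 16; 0.00418). They were -0.28 for the interferon response (2 lower of 15; 0.00361) and -0.24 for ribosomal proteins (18 lower of 44; 5.01e-11). Upward medians were 0.19 for proteasome subunits (4 higher and 1 lower of 31; 0.00361) and 0.26 for heat shock and chaperones (0 of 23; 0.00382). In 4 other settings the 6 lists stayed past the threshold at adjusted p from 5.36e-12 to 0.0255. The changes run with transcript length across genes (Spearman rho 0.27), and with that trend removed the 6 lists were still called, with smaller medians for the respiratory chain (-0.14) and ribosomal proteins (-0.11; camera adjusted p = 0.00172). The medians of the other 4 were then -0.13 for the tricarboxylic acid cycle, -0.27 for the interferon response, 0.24 for proteasome subunits and 0.26 for heat shock and chaperones.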

How the results depend on the processing

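Median-of-ratios scaling, removal of the transcript length trend and the choice of Hdac3 came after the result was seen; the other alternatives were planned. With only the groups compared, genes differing between KO and WT fell to 748 at ZT10 and rose to 2270 at ZT22, and those between the times were 2457 in WT and 3547 in KO. The SD over genes of a library's deviation from its group mean was 0.157 to 0.242 in KO ZT10. It was 0.136 to 0.155 in WT ZT10 and 0.125 to 0.163 in the libraries of ZT22. The main fit takes 1 spread per gene from all groups, so its standard errors do not show the larger spread of KO ZT10. Whether this gave the change of counts was not tested. With the length trend removed the test of the difference between times called 11, a rise whose cause was not tested either. Leaving out 1 library in turn gave 847 to 1562 genes for KO against WT at ZT10, 1035 to 2372 at ZT22, 1290 to 2929 for ZT22 against ZT10 in WT, 3328 to 4247 in KO and 2 to 77 for the difference between times. The low ends came without WT ZT10 replicate 3 (847), WT ZT22 replicate 2 (1035 and 1290) and KO ZT22 replicate 1 (3328). Without KO ZT10 replicate 3 the counts were 1243, 2372, 2929, 4080 and 47. Hdac3 reversed: its log2 difference between ZT22 and ZT10 in KO was 0.18 ± 0.49, not called, and -0.64 ± 0.20 without KO ZT10 replicate 3 (adjusted p = 0.0218), the library in which it was low; it was 0.60 without KO ZT10 replicate 2.

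Of 395 named gene results, 291 stayed called or stayed not called in each alternative, and the called ones among them also stayed within 1.5 times their value. Values of results that were not called were not held to that limit. A pseudocount of 0.1 called 1439, 1757, 2320, 4225 and 4 genes, no filter 1344, 1838, 2502, 4260 and 4, and robust empirical Bayes 1424, 1826, 2379, 4226 and 4. The replicate block called 1411, 1741, 2385, 4195 and 5. Residual correlations between libraries were -0.134 to 0.21 for the same replicate number and -0.2 to 0.135 for others. Those for the same number were mostly positive and the others mixed, so no strong pairing was seen and a weak one is not excluded. Scaling called 1405, 1827, 2315, 4217 and 3 genes. Of 52 list calls, scaling kept 49, length removal 44, the replicate block 50 and leaving out KO ZT10 replicate 3 kept 50, while an estimated correlation kept 0. New list calls numbered 6, 6, 5, 12 and 0 in these settings; the 12 included glucose uptake and glycolysis (adjusted p = 0.0275) and fast fibre genes (0.0275) for KO against WT at ZT10. Lists lost in the time comparisons with length removed were, in WT, fatty acid oxidation, fast fibre and immediate early genes (adjusted p = 0.0883 each) and ribosomal proteins (0.334), and in KO fast fibre (0.064) and sex-linked genes (0.0567). Planned edgeR and DESeq2 tests, size factors and the filter on low counts were not run, since they need counts. Values are at the level of genes, so loss of single exons cannot be seen, and depth was estimated, so no counting limit is given for low values.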

Other observations

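The tests of exchanged labels, Thra reads, lost autorepression, a batch between the times, a WT library under the KO label and a different Hdac3 allele were chosen after the result was seen.

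Nr1d1 was higher in libraries labelled KO at both times. Exchanged genotype labels are argued against by the 6 clock genes with REV-ERB and ROR elements, whose lower median log2 difference of the 2 times was 1.311, where an exchange needs a value below 0. Reads moved from the count of the overlapping gene Thra to that of Nr1d1 are argued against too, since the fall of Thra would give at most 3.9% of the rise. Reads from the overlap counted as Nr1d1 without a fall of Thra were not tested. For lost autorepression with a truncated transcript still counted, the test found 5 of those 6 genes called higher at both times. It cannot decide this explanation, since it reads other genes and not the transcript of Nr1d1. Exon-level values were not analysed here, so lost autorepression with a truncated transcript stays a hypothesis. Genes flanking the targeted loci and inherited with them are argued against as the main cause of the calls, since 12 of 199 genes within 5 Mb (6.0%) against 697 of 9700 elsewhere (7.2%) were called at both times (one-sided Fisher exact p = 0.773). The shares were 13.6% against 14.3% at ZT10 (one-sided Fisher exact p = 0.649) and 20.6% against 18.3% at ZT22 (one-sided Fisher exact p = 0.227), so a small excess near the loci at ZT22 is not excluded.

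Many genes were called between ZT22 and ZT10. The transcript length trend between the times is argued against as the whole cause, since 18.42% of genes were called in WT once it was removed, against 24.15% before. Of those 1824 genes, 1368 had been called before. A library or processing batch between the times could be a cause: the lowest length-weighted sum at ZT10 lay 40360 above the highest at ZT22, and 503 to 642 genes were at 0 at ZT10 against 240 to 365 at ZT22. The processed pseudogene Rpl31-ps12 was at 0 to 1.39 FPKM in the 6 libraries of ZT10 and 11.2 to 37.4 FPKM in the 6 of ZT22, and Rpl37rt at 0 to 0.46 and 6.85 to 17.8 FPKM. Such copies resemble their parent genes, so a difference in mapping or counting between the times could also give this, which was not tested. Each time was 1 set of libraries, so batch and time of day cannot be told apart. The opposite changes of Arntl and Dbp in WT are what a change of time of day would also give, which was not tested apart from batch.

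Library KO ZT10 replicate 3 stood apart. It lay at least 2-fold outside the other 11 libraries for 28 of 4192 genes with a mean of 10 FPKM or more, against 0 to 3 genes for each other library. Hdac3, which encodes a corepressor enzyme that REV-ERB receptors recruit, was at 6.48 FPKM in it, against 39.2 and 40.5 in the other KO libraries of ZT10 and 31.3 to 35.8 in the 6 WT libraries. At ZT22 it was at 20.4, 20.6 and 37.95 FPKM in KO, the first 2 at 53.8% and 54.3% of the last.

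A WT library under the KO label is argued against by Nr1d1 in KO ZT10 replicate 3, at 359.3 FPKM against a highest WT value of 54.0. Chance spread of single genes stays open: 0.191% of genes (8 of 4192, Hdac3 included) had a lowest library as far below the next, under the 1% set in advance, but Hdac3 was picked for its low value, which voids that test, and 6 of the 8 were lowest in this library. A different allele of Hdac3 in that animal could also lower it, to 16.3% of the mean of the other KO libraries of ZT10, but no value here decides it, and the labels name no Hdac3 allele.

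The 10 splits of 6 libraries are too few for a share under 0.05. In each pairwise comparison 1 split, the real one, gave as many genes: KO against WT called 1425 at ZT10 and 1826 at ZT22 with 1 as the highest other count, and ZT22 against ZT10 called 2404 in WT and 4239 in KO with 0 as the highest other count.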
